A study of Homo sapiens with 4 samples.

How the data were processed

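Total RNA of SKOV3 and ES2 cells, treated with YY-15 for 48 h or left untreated, was sequenced in 4 libraries, 1 per group. Per the labels' protocols, messenger RNA was selected by its poly(A) tail, second-strand cDNA was marked with dUTP so that the libraries keep strand, and fragments were sequenced from both ends after PCR, with no molecular identifiers described. The labels name different sequencers in different fields. Whether the library of a group came from 1 culture or several is not given in the sources used here.

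Per the submitters' processing notes, the tools were cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, with no role or order stated. Those notes name the build mm10, a mouse build, yet all 38558 gene identifiers in the deposited table are human Ensembl identifiers. Of these, 35576 were found in GENCODE 29, a human annotation on GRCh38, and 35536 of them (99.9%) overlapped the same gene there, so the coordinates are given as GRCh38. Per the file headers, the authors deposited FPKM (fragments per kilobase of transcript, scaled to library size) and counts for each library, in 1 table of the whole series. The deposited counts are whole numbers but are treated as estimated counts: over 200 genes per library have a count of 1 beside an FPKM above 0 and under 0.001, which a count of reads would not give. Whether the counting used strand is not given in the sources used here. Genes that overlap another measured gene on the same strand are reported as uncertain, and so are near-identical copies. Overlaps on opposite strands, which would matter if counting ignored strand, are not counted among these.

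Columns were matched to samples by the line and by control or dose in their headings. All 8 columns of values were used and none was left over. The 4 µM dose appears in these headings only.

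The design fixed before the data were examined compares YY-15 with control within each line, the 2 ratios with each other, and the untreated lines. With 1 library per group, a difference within a line or between the lines' ratios leaves no residual degrees of freedom. A model of an effect common to both lines would leave 1 and was not fitted. The design's measure of size was used: log2((YY-15 FPKM + 1)/(control FPKM + 1)), with a pseudocount of 1, over genes with an FPKM of 1 or more in at least 1 of the libraries compared. A 2-fold difference is a log2 ratio of 1 or more in size, and 4-fold was required between the untreated lines. For a named gene, an exact Clopper-Pearson 95% interval was computed for the log2 ratio of library shares from the estimated counts and the totals of both libraries. It covers counting error only, not the spread between cultures, and reads multiplied by PCR are not independent molecules. A count of 0 was taken to allow up to 3 counts.

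The 36 gene lists were also fixed before the data were examined. A list with at least 5 measured members was set against 10000 random lists of the same size, drawn from 20 bins of mean expression within the line. It stands apart where its median lies below percentile 2.5 or above percentile 97.5 of the random medians. Members of a list vary together, which random lists do not copy, so this describes the libraries only. The genes named in the text followed a rule fixed at the same time. It took the 12 highest and 12 lowest ratios per line at an FPKM of 5 or more, the 8 per direction largest in both lines, up to 4 per list by mean absolute ratio, and 5 per direction between the untreated lines. Genes without a symbol, small RNA and antisense names, pseudogenes and Y-linked genes were left out. Genes shared at 2-fold by both lines, component and overlapping genes, and members of pathways were named after their values were seen.

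The calculation was tested on simulated counts for the real genes. Of 50 genes simulated at 4-fold higher in ES2, 50 passed the 2-fold size, and of 50 at exactly 2-fold higher 2 did, because the pseudocount understates ratios. In SKOV3 these were 50 and 2. Among genes simulated as unchanged, 1 of 12011 in ES2 and 7 of 12594 in SKOV3 passed. The simulated libraries held counting noise only, without spread between cultures, a trend with GC content or reads shared between genes. These shares are therefore not a rate of false calls in the real libraries. Alternatives were pseudocounts of 0.1 and 5, no filter and a filter at an FPKM of 5, rescaling to a sum of 1000000 per library (TPM), centring on the median, and sizes of 1.5-fold and 3-fold. After the data were seen, 3 were added: removing the trend on transcript length and GC content by a local regression with a span of 0.3, leaving out read-through genes, and estimated counts scaled to 1000000 per library. In the last, the pseudocount of 1 and the filter of 1 applied to the scaled counts. Transcript length and GC content came from GENCODE 29 and were found for 97.3% of ES2 and 97.2% of SKOV3 genes past the filter. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.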

Results

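RNA was sequenced from 2 established human ovarian cancer cell lines, ES2 and SKOV3, after 48 h with or without YY-15, a compound known in the labels only by this code name. The column headings of the deposited table give the treated libraries a dose of 4 µM. Each of the 4 groups (ES2 control, ES2 YY-15, SKOV3 control and SKOV3 YY-15) held 1 library, so there was no replicate check, no test and no p-value for any difference, and every ratio below compares a pair of libraries. The estimated counts summed to 63900880 in ES2 control, 66684550 in ES2 YY-15, 67431058 in SKOV3 control and 62522202 in SKOV3 YY-15. Between 11781 and 12850 genes per library had an FPKM of 1 or more. Ratios are log2((YY-15 FPKM + 1)/(control FPKM + 1)), which understate the difference of genes with low FPKM. Intervals in brackets are exact 95% intervals of the log2 ratio of estimated counts, each divided by its library's total, without a pseudocount, and they cover counting error only.

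What YY-15 treatment did to SKOV3 expression was the first question the design addressed. Genes of the integrated stress response, NF-kB and inflammatory cytokine genes, and genes of the ERK feedback loop were higher in the SKOV3 YY-15 library than in its control. Genes of DNA replication, tubulin genes, mitotic genes, proteasome subunit genes and heat shock genes were lower. Among 13294 genes with an FPKM of 1 or more in either SKOV3 library, 221 were at least 2-fold higher and 174 at least 2-fold lower, together 2.97%. At least 4-fold differences were seen for 43 of them, 30 higher and 13 lower. Both counts depend on the pseudocount. The libraries correlated at r = 0.959 across these genes, on log2(FPKM + 1), where genes are not independent replicates.

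GDF15, a stress-responsive secreted factor, had the highest ratio in SKOV3 among genes reaching an FPKM of 5. It stood at 0.738 FPKM in the control and 24.8 FPKM in the YY-15 library, a log2 ratio of 3.89 [4.80 to 5.37]. The gene (ENSG00000130513) lies on chromosome 19 at 18374731 to 18389176 in GRCh38 coordinates. IL1A, encoding interleukin-1 alpha (ENSG00000115008, chromosome 2, 112773925 to 112784493), was at 4.53 against 69.9 FPKM, a log2 ratio of 3.68 [3.84 to 4.07]. CHAC1, a glutathione-degrading enzyme (ENSG00000128965, chromosome 15, 40952962 to 40956512), was at 1.43 against 26.5 FPKM, a log2 ratio of 3.50 [4.01 to 4.42]. DDIT3, which encodes the stress transcription factor CHOP (ENSG00000175197, chromosome 12, 57516588 to 57521737), was at 5.12 against 46.0 FPKM, a log2 ratio of 2.94 [3.02 to 3.30]. Next came IL6 (2.87), CXCL8 (2.75), TRIB3 (2.60), G0S2 (2.59), TXNIP (2.57), GADD45A (2.47) and PPP1R15A (2.46), the last encoding the phosphatase subunit GADD34. The read-through gene RPL36A-HNRNPH2 also ranked here at 2.75, but its exons are those of its neighbours and its value is uncertain.

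At the other end, HRH1, the histamine H1 receptor gene (ENSG00000196639, chromosome 3, 11137093 to 11263557), was at 5.91 FPKM in SKOV3 control and 0.0860 in the YY-15 library, a log2 ratio of -2.67 [-6.64 to -5.59]. PEG10, an imprinted retrotransposon-derived gene (ENSG00000242265, chromosome 7, 94656325 to 94669695), had a ratio of -2.16 [-3.71 to -3.31]. HSPA8, the constitutive Hsc70 chaperone (ENSG00000109971, chromosome 11, 123057489 to 123063230), was at 282 against 70.7 FPKM, a ratio of -1.98 [-2.01 to -1.97]. FAM111B (-1.91), the deiodinase gene DIO2 (-1.83) and MCM5 (-1.75), a subunit of the replicative helicase, were also among the 12 lowest. HSPA1A (-1.89) and HSPA1B (-1.86) are near-identical copies whose reads could be split by the counting. The values of TOMM6 (-2.18), UPK3BL1 (-2.06) and RPS10-NUDT3 (-1.78) are uncertain because each overlaps another measured gene on the same strand. MT-TF (-1.80) is a mitochondrial transfer RNA, a class that poly(A) selection captures poorly.

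The integrated stress response list, genes activated by the transcription factor ATF4, had a median log2 ratio of 1.45 in SKOV3. Of its 22 measured members, 21 were above 0 and 16 were at least 2-fold higher, while random lists of matched expression had medians between -0.19 and 0.14 in 95% of draws. Besides CHAC1, DDIT3, TRIB3 and PPP1R15A, it shares SESN2 (1.99) with the p53 target list. The NF-kB and inflammatory cytokine list had a median of 1.32, with all 17 measured members above 0 and 11 at least 2-fold higher, against -0.20 to 0.19 in random lists. IL1B, the interleukin-1 beta gene, was at 1.76 FPKM in the control against 11.7 in the YY-15 library. The 11 ERK feedback genes are induced by MAP kinase signalling, and several of them restrain it. Their median was 1.25 against -0.21 to 0.25 in random lists. All 11 were above 0 and 7 at least 2-fold higher, among them PHLDA1 (2.19), DUSP5 (1.76), ETV5 (1.70) and DUSP6 (1.55). Immediate early genes had a median of 0.79 against -0.31 to 0.20, with 9 of 11 above 0 and 3 at least 2-fold higher, including ATF3 (2.09), KLF4 (2.06) and DUSP1 (1.07).

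Smaller medians above the random range were found for 5 further lists in SKOV3. YAP/TEAD targets had a median of 0.34, with 9 of 10 above 0 and ANKRD1 at 1.65. FOXO targets had 0.29, with 9 of 9 above 0 and TXNIP at 2.57. The median of the FOXO list lay inside the random range with a pseudocount of 0.1 and with the trend on transcript length and GC content removed. Autophagy and lysosome genes had 0.26, with 17 of 21 above 0 and the autophagy receptor gene SQSTM1 at 0.90. Extracellular matrix genes had 0.25, with 10 of 13 above 0 and COL6A1 at 0.82. Ferroptosis genes had 0.20, with 10 of 15 above 0. The ferroptosis members furthest from 0, CHAC1, SAT1 (1.23) and SLC3A2 (1.15), include CHAC1 and SLC3A2 of the integrated stress response list.

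Of the lists below the random range in SKOV3, the G1/S and DNA replication list had the lowest median, -1.11 against -0.18 to 0.15 in random lists. Among its 22 members 21 were below 0 and 13 at least 2-fold lower. They included MCM5, PCNA (129 against 44.9 FPKM, -1.50), the ribonucleotide reductase subunit gene RRM2 (-1.46) and thymidine kinase TK1 (-1.45). All 11 tubulin genes were below 0, with a median of -0.99 against -0.32 to 0.18, and 4 were at least 2-fold lower: TUBB4B (340 against 125 FPKM, -1.44), TUBA1B (-1.32), TUBB3 (-1.17) and TUBB2A (-1.07). G2/M and mitosis genes had a median of -0.67, with all 21 below 0 and 3 at least 2-fold lower, KIF20A (-1.61) and MKI67 (-1.13) among them. All 18 proteasome subunit genes were below 0, with a median of -0.61 and PSMD1 at -1.03. All 15 heat shock genes were below 0, with a median of -0.59. At least 2-fold lower were 6 of them, among them HSPA8 and HSP90AA1 (342 against 107 FPKM, -1.66).

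A further 5 lists stood below the random range in SKOV3 by less. Ovarian carcinoma markers had a median of -0.52 over 7 genes, with CD24 at -0.79 and CD44 at 0.59; after rescaling each library to a sum of 1000000 the median was -0.04 and inside the random range. Glycolysis genes had -0.38, with 15 of 16 below 0 and the phosphoglycerate mutase gene PGAM1 at -1.45. Homologous recombination and mismatch repair genes had -0.37, with 18 of 19 below 0 and FANCD2 at -0.87. Histone genes had -0.33, with H2AX at -1.17, and a pseudocount of 5 moved the median to -0.15, inside the random range. Nuclear oxidative phosphorylation genes had -0.29, with 23 of 24 below 0 and ATP5MC1 at -0.89. The random lists understate the spread of real lists, whose members vary together, so standing apart from them describes these libraries and is not a test.

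The other 12 lists had SKOV3 medians inside the random range. The p53 targets had a median of -0.01 although 5 of 18 were at least 2-fold higher, led by GDF15, GADD45A, SESN2 and the cell cycle inhibitor gene CDKN1A (1.67). Among p53 targets with an FPKM of 5 or more in at least 1 SKOV3 library, the median was 0.64 and above the random range. GDF15, SESN2 and CDKN1A passed that filter only through the YY-15 library. This median therefore cannot tell a rise of the list from the selection of its members. Endoplasmic reticulum chaperone and unfolded protein response genes had -0.12, with XBP1 at 1.20 and SDF2L1 at -0.88. Mitochondrially encoded protein genes had -0.29 (MT-CYB -0.62), BCL2 family and caspase genes 0.18 (PMAIP1 1.28), and hypoxia genes -0.07 (VEGFA 1.42). The BCL2 family and caspase median lay above the random range at a pseudocount of 5 (0.15) and after rescaling to a sum of 1000000 (0.27). MYC and ribosome biogenesis genes had 0.02 (MYC 1.23), mesenchymal genes 0.10 (FN1 1.01) and epithelial genes -0.09 (KRT8 -1.08). The mesenchymal median was 0.32 at an FPKM of 5 or more and 0.26 after the same rescaling, both above the random range. Interferon response genes had 0.12 (IFIT2 0.61), NRF2 antioxidant genes 0.03 (NQO1 -0.68), cholesterol synthesis genes -0.09 (INSIG1 0.57) and ribosomal protein genes 0.05 (RPL3 0.36).

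**Figure D1:**
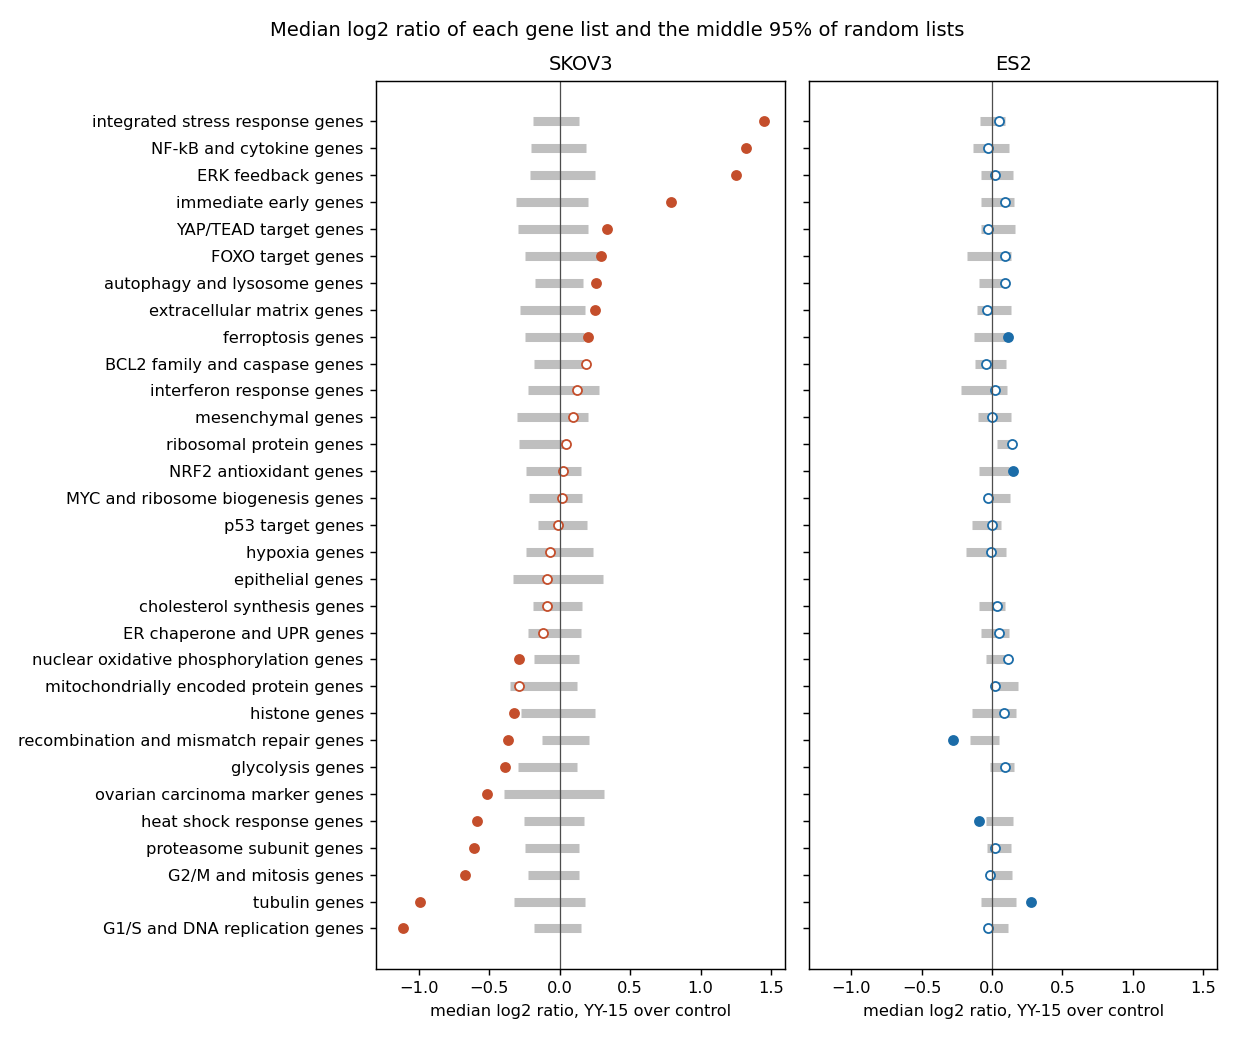
Median log2 ratio (YY-15 over control, x axis) of each gene list in SKOV3 (left) and ES2 (right), with the range of medians holding 95% of 10000 random lists of matched expression as grey bars; filled points lie outside that range. In SKOV3 the integrated stress response list is at 1.45 and the DNA replication list at -1.11, and in ES2 the medians lie between -0.28 and 0.28.

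**Figure D2:**
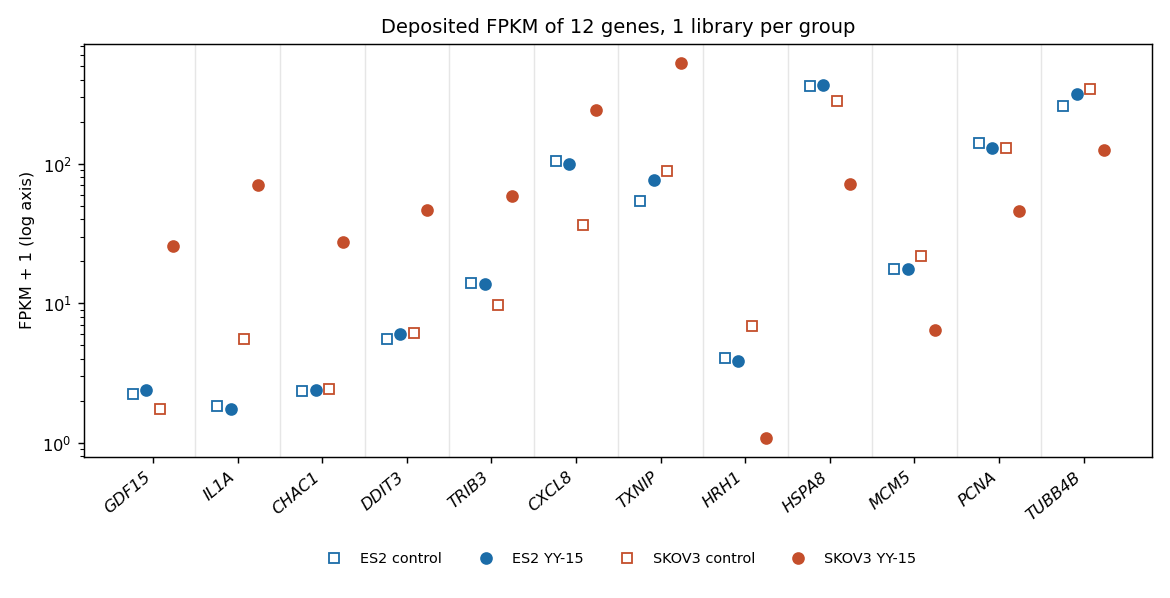
FPKM + 1 (log axis) of 12 genes in the ES2 and SKOV3 libraries, with open squares for controls and filled circles for YY-15, 1 library per group. GDF15 is at 0.738 FPKM in SKOV3 control and 24.8 in SKOV3 YY-15, and at 1.25 and 1.39 in the corresponding ES2 libraries.

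The same comparison in ES2 gave few genes of known function with large ratios. Tubulin genes were slightly higher in the ES2 YY-15 library, and homologous recombination and mismatch repair genes were lower. The mitotic kinesin genes CENPE and KIF20B were among the lowest. Of 12341 genes with an FPKM of 1 or more in either ES2 library, 43 were at least 2-fold higher and 60 at least 2-fold lower, together 0.835%, and 29 of these 103 had a protein-coding transcript. The log2 ratios had a standard deviation of 0.262 across genes, against 0.425 in SKOV3, and the ES2 libraries correlated at r = 0.986 across genes.

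Most of the genes with large ratios in ES2 overlapped another measured gene on the same strand, where reads cannot be assigned with certainty. This held for 57 of the 87 at least 2-fold different genes other than small RNA genes (65.5%), against 9.83% of all 12236 such genes past the filter. In SKOV3 the corresponding shares were 23.4% and 10.4%. Among the 12 lowest in ES2, NME1-NME2, RPL36A-HNRNPH2, RPL17-C18orf32, RPS10-NUDT3, ATP6V1G2-DDX39B and SENP3-EIF4A1 are read-through genes that span their neighbours. NME1-NME2 and RPL17-C18orf32 had a count of 0 in the YY-15 library. The floor was 3 counts, a one-sided limit, with the control count taken as exact. As a share of the library they were then at least 355.5-fold and at least 320.0-fold lower. These limits cover counting error only, not the assignment of reads between overlapping genes, so they bound no change in RNA. Summed with the counts of their component genes, NME1-NME2 and RPL17-C18orf32 had log2 ratios of 0.21 and 0.01. Their component genes were instead higher in the YY-15 library: NME1 (0.19), NME2 (0.32), RPL17 (0.04) and C18orf32 (0.26). So were RPS10 (0.50), NUDT3 (0.14), EIF4A1 (0.40) and SENP3 (0.39), components of RPS10-NUDT3 and SENP3-EIF4A1. One of the deposited entries named MATR3 (ENSG00000280987) had a ratio of -1.86, and the overlapping entry of that name 0.30. The decoy receptor gene TNFRSF6B (-1.93) lies within RTEL1-TNFRSF6B, whose ratio was 0.35.

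ZNF395 (6.38 against 2.26 FPKM, -1.18 [-1.61 to -1.39]), CENPE (8.19 against 3.36 FPKM, -1.08 [-1.35 to -1.21]), FAM111B (-1.02) and KIF20B (19.6 against 9.35 FPKM, -0.997 [-1.12 to -1.02]) were the only genes among the 12 lowest in ES2 with no such overlap. With the trend on transcript length and GC content removed, ZNF395 was at -1.29, while CENPE (-0.82) and FAM111B (-0.81) were under 2-fold, as was KIF20B (-0.74), which had been just under 2-fold before. Of the 12 highest, SPSB3 (0.80), the stromelysin gene MMP3 (4.10 against 7.64 FPKM, 0.76 [0.75 to 1.06]), ID3 (16.2 against 28.0 FPKM, 0.75 [0.70 to 0.87]), AVPI1 (0.59) and TRBJ2-1 (0.62) had none. The interval of the short segment TRBJ2-1, 0.04 to 1.27, reached close to 0. NDUFC2-KCTD14 (1.78), BOLA2 (1.42), CDC42EP2 (1.32), OVCA2 (0.95), RNASEK-C17orf49 (0.89), TSFM (0.72) and HNRNPUL2-BSCL2 (0.70) overlap other genes and are uncertain.

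Across ES2 genes the log2 ratio followed the GC content of the transcripts (Spearman rho = 0.425 over 11557 genes that are in no list), with a median of -0.21 in the bin of lowest GC content and 0.08 in the bin of highest, of 10 bins. The same rho was 0.0159 in SKOV3. Of the 29 lists with at least 5 measured members, 5 stood apart in ES2, where 1.45 of as many random lists would. Members of real lists vary together, so more of them can stand apart without an effect of treatment. Homologous recombination and mismatch repair genes had a median of -0.28 against -0.16 to 0.05 in random lists, with 17 of 19 below 0 and BRCA2 at -0.64. With the trend on transcript length and GC content removed, their median was -0.19 and still below the random range. All 10 measured tubulin genes were above 0, with a median of 0.28 against -0.08 to 0.17, and 0.19 with the trend removed; TUBB4B was at 0.29. TUBB3, at 0.33, is uncertain because it overlaps ENSG00000198211, whose estimated count was 0 in ES2 control and 1148 in ES2 YY-15. Heat shock genes (-0.09, HSP90AA1 -0.34), NRF2 antioxidant genes (0.15, OSGIN1 0.24) and ferroptosis genes (0.11) stood apart as deposited. They did not with the trend removed, at -0.01, 0.09 and 0.07.

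The ES2 medians of the remaining 24 lists lay inside the random range. Among them, integrated stress response genes had 0.05, NF-kB and cytokine genes -0.03, ERK feedback genes 0.02 and immediate early genes 0.09. G1/S and DNA replication genes had -0.03, G2/M and mitosis genes -0.02 (CENPF -0.86), proteasome subunit genes 0.02, histone genes 0.08 and p53 targets 0.00. Ribosomal protein genes had 0.14, with 25 of 26 above 0, nuclear oxidative phosphorylation genes 0.11, mitochondrially encoded protein genes 0.02, glycolysis genes 0.09 and autophagy and lysosome genes 0.10. The medians were 0.05 for endoplasmic reticulum chaperone genes, 0.04 for cholesterol synthesis, -0.05 for BCL2 family and caspase genes, 0.02 for interferon response and -0.00 for hypoxia. They were -0.03 for MYC and ribosome biogenesis, -0.00 for mesenchymal genes (ZEB1 -0.89), -0.03 for extracellular matrix, 0.09 for FOXO targets and -0.03 for YAP/TEAD targets. With the trend removed, the NF-kB and cytokine (0.10), nuclear oxidative phosphorylation (0.10) and autophagy and lysosome (0.11) medians lay above the random range.

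Some lists had fewer than 5 measured members and no median. These were metallothionein genes (4 measured in ES2 and 3 in SKOV3), aryl hydrocarbon receptor targets (3 in each line), and in ES2 also epithelial genes (3) and ovarian carcinoma markers (1). Of metallothioneins, MT2A had ratios of 0.25 in ES2 and -0.20 in SKOV3, and of receptor targets, TIPARP had 0.11 and 0.39. Of leukocyte markers only CD68 reached an FPKM of 1, of endothelial markers only CDH5 did so, in ES2, and of erythroid markers none did.

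Whether both lines responded alike was asked across the 11028 genes measured in both. The log2 ratios of the lines were uncorrelated (Pearson r = -0.02, Spearman rho = -0.04, across genes, which are not independent replicates). Genes at least 2-fold higher in SKOV3 had a median ratio of 0.05 in ES2, where 93 of 155 lay above 0. Those at least 2-fold lower in SKOV3 had an ES2 median of -0.00, where 62 of 123 lay below 0. The median over all ES2 genes past the filter was -0.02. At least 2-fold higher in both lines were 5 genes, against 0.309 for independent lists: BEST1, the read-through gene RAB4B-EGLN2, the small RNA gene RN7SL2 and the pseudogenes RPL23AP82 and RPL29P4. At least 2-fold lower in both were 7, against 0.435. FAM111B, a protease gene (ENSG00000189057, chromosome 11, 59107185 to 59127410), was the only one of these 7 with a symbol that is neither a microRNA nor a read-through gene. It stood at 5.87 against 2.40 FPKM in ES2 (-1.02 [-1.42 to -1.16]) and 6.94 against 1.11 FPKM in SKOV3 (-1.91 [-2.83 to -2.46]). With the trend on length and GC content removed its ES2 ratio was -0.81, under 2-fold. Opposite 2-fold differences were found for 8 genes, against 0.794 for independent lists. They include the read-through gene RPL36A-HNRNPH2 and the pseudogenes GTF2IP1 and HERC2P3. Since opposite differences exceeded independent lists too, the excess in the same direction is not evidence of a shared response. No difference between the lines was tested, since each rests on 1 library per group.

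With smaller ratios of the same sign in both lines, TXNIP had 0.49 in ES2 and 2.57 in SKOV3, and DUSP1, a MAP kinase phosphatase gene, had 0.46 and 1.07. EVA1B (0.51 and 0.79), CD68 (0.44 and 0.55), NAT14 (0.44 and 0.51) and HEIH (0.43 and 1.10) were also higher in both. So were CDC42EP2 and NDUFC2-KCTD14. Of these, CD68 overlaps ENSG00000264772, whose ES2 ratio was -1.24. CDC42EP2 overlaps ENSG00000285816, at -1.51 in ES2 and 0.95 in SKOV3. NDUFC2-KCTD14 is a read-through gene whose component NDUFC2 was lower, at -0.30 in ES2 and -0.74 in SKOV3. Lower in both were the mitotic spindle gene ASPM (-0.79 and -1.02), the kinetochore gene CENPF (-0.86 and -0.72), BRCC3 (-0.60 and -0.76), LEO1 (-0.56 and -0.59) and SLTM (-0.56 and -0.61). With the trend removed, ASPM was at -0.56, CENPF at -0.67, BRCC3 at -0.63, LEO1 at -0.48 and SLTM at -0.53 in ES2. Of the genes higher in both lines, EVA1B and DUSP1 were then at 0.39 in ES2, CD68 and HEIH at 0.35 and NAT14 at 0.32. TXNIP was at 0.52. ATP6V1G2-DDX39B and SENP3-EIF4A1 were lower in both but are read-through genes.

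**Figure D3:**
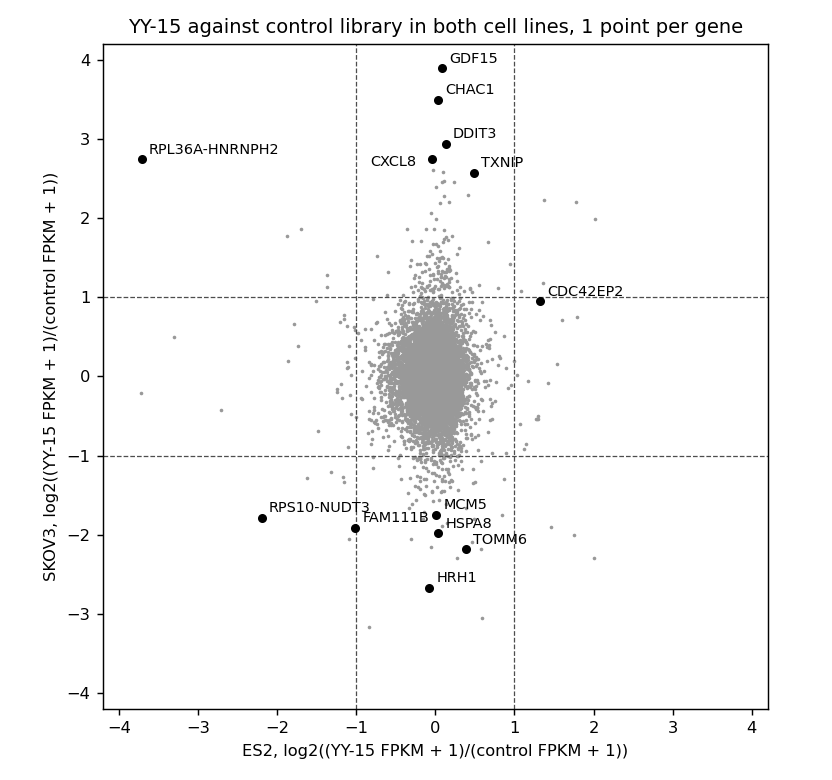
Log2 ratio of YY-15 over control in ES2 (x axis) against SKOV3 (y axis), 1 point per gene with an FPKM of 1 or more in both lines, with dashed lines at 2-fold and named genes in black. The points spread along the SKOV3 axis, GDF15 lies at 0.08 in ES2 and 3.89 in SKOV3, and r across genes is -0.02.

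The untreated libraries differed more between the lines than treated from untreated within a line. Of 14024 genes with an FPKM of 1 or more in either control, 674 were at least 4-fold higher in SKOV3 and 456 in ES2. ERBB2, the HER2 receptor gene that SKOV3 is known to overexpress (ENSG00000141736, chromosome 17, 39687914 to 39730426), was at 152 FPKM in SKOV3 control and 0.0317 in ES2 control, so the labels of the lines matched. CD24 (551 against 0.717 FPKM), DHRS2 (129 against 0.0118), APOL1 (104 against 0.0576) and RRAD (121 against 0.403) were also far higher in SKOV3 control than in ES2 control. Conversely, ES2 control had 285 FPKM of SERPINB2, which is listed at 0 in SKOV3 control. The chemokine gene CXCL5 (216 against 0.0230), the pentraxin gene PTX3 (215 against 0.509), FLNC (106 against 0.0216) and KRTAP2-3 (161 against 0.585) were likewise higher in ES2. Several genes that were higher in the SKOV3 YY-15 library already stood high in ES2 control: CXCL8 at 103 FPKM, G0S2 at 342 and ANKRD1 at 187. Those with the highest SKOV3 ratios did not: ES2 control had GDF15 at 1.25 FPKM, IL1A at 0.849, CHAC1 at 1.35, DDIT3 at 4.51 and IL6 at 0.0504.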

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

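All tests below were chosen after the patterns they weigh had been seen in the data. Those on repair, tubulin and heat shock genes and on overlapping genes were also chosen after test results were seen. The other tests were chosen before their own results were seen.

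Tubulin genes stood apart in opposite directions in the lines: their median log2 ratio was 0.28 in ES2 and -0.99 in SKOV3, a difference of -1.27 that was not tested. RPL36A-HNRNPH2 also differed in direction, at -3.71 in ES2 and 2.75 in SKOV3, a difference of 6.46 that was not tested either.

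The first pattern weighed is that in SKOV3, where stress response and cytokine genes were higher and replication and tubulin genes lower in the YY-15 library. A bias of transcript length or GC content is argued against as its whole cause, since the median of the ATF4 list was 1.43 with that trend removed, against 1.45 before. RNA of ES2 in the library is argued against too: the 19 genes at 50 FPKM or more in ES2 control and under 1 in SKOV3 control had a median of 0.348% of their ES2 level in the SKOV3 YY-15 library, and 0.208% in its control. The effect of YY-15 stays open as a hypothesis, because treatment, culture and library are confounded with 1 library per group.

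The second pattern is that of the ES2 lists. A bias of GC content between the ES2 libraries is a candidate cause of the trend across genes (rho = 0.425, and 0.310 to 0.496 within 3 bins of transcript length), while the trend with length (rho = -0.155) was too weak to decide. Together they may account for the heat shock list. Its median was -0.09 as deposited and, with the trend removed, -0.00807 and inside the random range. Repair genes (-0.19) and tubulin genes (0.19) still stood apart with the trend removed. That removal fitted length and GC content separately, although the GC trend rose from rho = 0.310 in short transcripts to 0.496 in long ones. It may therefore correct too little, and cannot tell whether the trend accounts for the repair and tubulin lists in full. A response shared with SKOV3 across all genes is argued against by r = -0.0237 between the lines with the trend removed, though the repair genes had a median of -0.36 in SKOV3 too. A real difference in GC-rich and GC-poor transcripts would give the same trend and stays open.

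The third pattern is the large ratios of overlapping genes in ES2. Reads shared between overlapping genes are a candidate cause, since 65.5% of the at least 2-fold different genes overlapped another, against 9.83% of all genes. For read-through genes at least 2-fold different, counts summed with their component genes had a median absolute log2 ratio of 0.168. This median and the next value pool 26 values of both lines, not of ES2 alone. That sum cannot tell shared reads from a real difference, because it would have moved by a median of 0.120 with the components unchanged. No biological explanation was tested for this pattern.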

How the results depend on the processing

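Removing the trend on transcript length and GC content, leaving out read-through genes, and scaling estimated counts to 1000000 were alternatives chosen after the data were seen. Without a filter and with centring on the median, each count of genes below stayed within 1.5 times its value in the report, and no ratio at or past 2-fold in the report changed sign under an alternative that was run. Genes at least 2-fold higher in ES2 (43 in the report) numbered 104 with a pseudocount of 0.1, 9 with 5, 13 at an FPKM of 5 or more, 282 after TPM rescaling and 124 at 1.5-fold. Those at least 2-fold lower in ES2 (60) numbered 196, 12, 20, 596 and 270 in that order, and 104 from estimated counts, where 62 were higher. In SKOV3, genes higher (221) numbered 548 with a pseudocount of 0.1, 93 with 5, 1115 after TPM rescaling, 916 at 1.5-fold and 458 from estimated counts. Genes lower in SKOV3 (174) numbered 365, 58, 748, 756 and 267 in that order, and 114 at an FPKM of 5 or more.

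Genes higher in both lines (5) numbered 14 with a pseudocount of 0.1, 0 with 5, 1 at an FPKM of 5 or more, 37 after TPM rescaling, 15 at 1.5-fold and 10 from estimated counts. Genes lower in both (7) numbered 14, 1, 3, 47 and 24 under the first 5 of these, and 4 without read-through genes. Genes differing in opposite directions (8) numbered 21, 2, 2, 84, 36 and 23 under all 6 in that order. Genes differing 4-fold between the untreated lines (1130) numbered 2583 with a pseudocount of 0.1, 285 with 5, 2591 after TPM rescaling, 1798 at 3-fold and 2274 from estimated counts. The shifts other than those from estimated counts and without read-through genes follow from construction: a smaller pseudocount or size passes more genes of low FPKM, a stricter filter fewer, and TPM rescaling raises all values and so acts like a smaller pseudocount and a lower filter. Leaving out read-through genes removes 3 of the 7 genes lower in both lines. For estimated counts a part can follow from construction too, since FPKM summed to only 233277 to 268615 per library while the pseudocount and filter stayed at 1. Estimated counts are also not divided by transcript length, and these parts were not told apart.

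The correlation between the lines stayed between -0.03 and -0.007. The number of lists standing apart was 5 or 6 in ES2 and 18 to 20 in SKOV3, but not always the same lists. In ES2 the ferroptosis list lay inside the random range with a pseudocount of 0.1, at an FPKM of 5 or more, after TPM rescaling and with the trend removed. Autophagy and oxidative phosphorylation genes lay above it with a pseudocount of 0.1, after TPM rescaling and with the trend removed, and mitochondrially encoded genes lay below it at an FPKM of 5 or more. In SKOV3 the ovarian marker list lay inside it with a pseudocount of 5, at an FPKM of 5 or more and after TPM rescaling. The cause of these list changes was not tested. Of the ratios of named genes under the alternatives, 549 in ES2 and 516 in SKOV3 differed from the reported ratio by no more than the distance from the count ratio to the farther bound of its counting interval, and 256 and 324 differed by more. NME1-NME2 and RPL17-C18orf32 in ES2, with no finite count ratio, are among the latter. Leaving out a replicate and blocking on replicate number were not run, because each group has 1 library. Depth limits mainly genes of low FPKM, since each library held at least 62522202 estimated counts.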

Other observations

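Pathways of the KEGG annotation in the deposited table, with 15 to 200 genes, were compared with random lists in the same way. The pathways below were singled out after their values were seen, and many pathways share genes. In SKOV3, 95 of 268 stood apart (53 higher and 42 lower), where 13.4 of as many random lists would. In ES2, 35 of 261 did (16 higher and 19 lower), where 13.1 of as many random lists would. Members of a pathway vary together, which random lists do not copy. With the trend on transcript length and GC content removed, 43 stood apart in ES2 (22 higher and 21 lower), of which 25 had stood apart in the same direction before. Complement and coagulation genes had a median log2 ratio of 0.44 in SKOV3, with 22 of 25 above 0. C3, the central complement component, was at 19.2 against 61.4 FPKM (1.63), complement factor B gene CFB at 9.29 against 28.9 FPKM (1.54), and the plasminogen activator genes PLAT and PLAU had ratios of 1.49 and 0.94. In ES2 the median of that pathway was 0.04 and inside the random range.

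Genes of the circadian rhythm pathway had a median of 0.37 in SKOV3, with 24 of 30 above 0, and -0.05 in ES2. The nuclear receptor gene NR1D1 was at 5.64 against 21.7 FPKM (1.78), NFIL3 at 13.2 against 30.1 FPKM (1.14), and DBP and PER1 both at 0.94, while CLOCK was at -0.17. Spliceosome genes had a median of -0.28 in SKOV3, with 109 of 128 below 0 and 8 at least 2-fold lower. Besides the heat shock genes HSPA8, HSPA1A and HSPA1B, these included the messenger RNA export gene ALYREF (-1.15), SRSF2 (-1.05), HNRNPM (-1.04) and LSM3 (-1.02). In ES2 the spliceosome median was -0.05, below the random range, and -0.03 with the trend on length and GC content removed.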
